A study of Bos taurus with 19 samples.

How the data were processed

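Single-nucleus RNA sequencing was done on bovine placenta collected at 6 stages of gestation, E60, E85, E110, E180, E240 and E280, where the number is the day of gestation. Per the labels' protocols, the tissue came from Holstein heifers that carried transferred embryos. Frozen tissue was homogenised in a nuclear lysis buffer, nuclei were stained with a DNA dye and sorted on a flow cytometer against debris and doublets, and libraries were made with droplet-based 3' chemistry of 10x Genomics. Each of the 19 deposited libraries holds a list of nucleus barcodes, a list of 21861 genes and a sparse matrix. The matrices hold counts of unique molecular identifiers (UMIs) per gene and nucleus as whole numbers with no normalisation, as deposited by the authors. Per the file headers they were written by Cell Ranger 8.0.1, while the submitters' processing notes name Cell Ranger 7.1.0 and Seurat. Which of these versions made the counts is open, and the genome build and annotation are not given in the sources used here, so no coordinates are printed. Genes are named by the symbols in the files. Of the 21861 genes, 4101 had no symbol and were tested by identifier only, and 64 symbols stood on more than 1 identifier (PAG1 and GNAS among them) and were left out of the gene lists.

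Library totals ran from 15.6 to 79.4 M UMIs and median depths from 1182 to 4926 UMIs per nucleus. Libraries of a stage were compared before any was averaged, by their shared barcodes, by the correlation of UMI totals per shared nucleus and by a chi-square of counts over genes. They proved to be repeated runs of the same nuclei, as the report describes, so the runs of a stage were averaged and counted as 1 sample. This leaves 6 samples, 1 per stage. The planned fit with a mean per stage then had no residual degrees of freedom. The fit therefore used 2 periods as its only term, early (E60, E85 and E110) against late (E180, E240 and E280), with stages as the replicates of a period. The planned test of any difference over the 6 stages and a test between single stages could not be run. Nothing in the labels says how many animals stand behind a stage, so every p-value measures the spread between these 6 samples.

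Nuclei with at least 300 genes, at least 500 UMIs and at most 5% mitochondrial UMIs were kept in the deepest run of each stage. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold called 0 or 1 doublet in 3 stages, so the 6% of nuclei with the highest scores were removed in every stage, a share set after these calls were seen. The remaining nuclei, between 6425 and 10837 per stage, were clustered together without batch integration (2000 variable genes, 40 principal components, 20 nearest neighbours, Leiden resolution 1 with leidenalg 0.10.2 and igraph 0.11.9). Nuclei of the other runs took the cluster of their barcode. The 38 clusters were named from marker sets fixed before the data were examined, as were the classes to compare, the gene lists, the rule for named genes, the tests and the alternatives in the closing section that are not called added there. The scoring rule for names was set afterwards. It took the mean standardised level of a class's markers, with at least 5 markers reaching 50 CPM (counts scaled to a common library total) in some cluster, at least 3 of them detected, a score of at least 0.2, and a runner-up from another lineage at no more than 40% of the best score. A marker under 15% of its highest cluster counted as background. PGR and ESR1 stand in the marker sets of both uterine epithelium and uterine stroma and were not used, and neither were keratins, CDH1, EPCAM and GRHL2 for trophoblast, since uterine epithelium shares them. RELN, a marker of lymphatic endothelium in the fixed sets, led clusters named binucleate. Clusters 7 and 17 scored for binucleate trophoblast and for uterine epithelium and stayed unnamed, as did 4 others with low marker levels or few UMIs. Uterine epithelium-like and uterine stroma-like nuclei were added as comparisons once their numbers were seen.

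For every class with at least 20 nuclei in a stage, raw counts were summed per library, averaged over the runs of the stage and rounded. edgeR 4.0.16 in R 4.3.3 (TMM normalisation, genes kept by its expression filter, robust quasi-likelihood test) compared late with early stages, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Trophoblast-like and binucleate-like nuclei fell below 20 at E280, so their late period holds E180 and E240. Mesenchymal nuclei fell below 20 at E180 and E280, which leaves E240 alone in their late period, and this lone sample is assumed to vary like the early ones. The planned contrast of E280 with E240 in these 3 classes could not be made for the same reason. For the added values of E280 beside E240 in the other classes, each stage is 1 sample, so no test was run. Ratios there carry an exact conditional binomial interval at 95% that covers counting error only and were computed with 0.5 counts added to both stages. Genes were named by the size of the ratio, and a list's median was placed among 10000 random lists of the same size and expression. The difference between binucleate-like and other trophoblast was tested as the interaction of class and period, with the stage as a block. Shares of nuclei were compared by an exact two-sided permutation test over the 6 stage means. With 3 stages against 3 its smallest possible p is 0.1. Shares of single stages carry exact Clopper-Pearson intervals at 95%, and a count of 0 is given with the share that 3 nuclei would make. CPM in the comparisons of late with early stages is scaled by TMM, and CPM named as raw is scaled by the UMI total of the class alone.

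Of 26 gene lists fixed beforehand, 25 had members in the files. They cover pregnancy-associated glycoproteins (PAG), the placental prolactin family, steroid metabolism, the prostaglandin and oxytocin pathway, transport of glucose, of amino acids and of iron, calcium and zinc, lipid handling, imprinted genes, S and G2/M phase, endoreduplication and cell fusion, angiogenesis, hypoxia and glycolysis, extracellular matrix, matrix remodelling, antigen presentation, interferon-stimulated genes, WNT, NOTCH and TGF-beta signalling, growth factor signalling, trophoblast transcription factors, the nuclear-encoded respiratory chain, ribosomal proteins, stress and immediate early genes, senescence and apoptosis, and haemoglobins. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over the lists of a comparison. PAG and prolactin genes are multigene families of similar sequence whose reads the counting can split or share, so single members are uncertain. Named genes are, per comparison, up to 8 per direction with the largest fold change among calls that kept the stages of both periods apart, with at least 20 CPM in the higher period, and the 14 list members with the smallest adjusted p at the same floor; other list members are named as examples.

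Alternatives were DESeq2 1.42.0, no filter on low counts, doublets kept, at least 1000 genes per nucleus, at most 1% mitochondrial UMIs, at least 100 nuclei per class, other cluster resolutions, centring per library, summed runs, every library as its own replicate with and without the replicate number as a block, a linear trend on the day of gestation, and each library left out. Added after the data were seen were each stage left out, the deepest run alone, and every library as its own replicate with 2 periods as the only term. The fits were tested on simulated data drawn from the means and library sizes of each class, with 200 genes changed. At a log2 fold change of 2 the test recovered 71.6% of changed genes for trophoblast, 67.2% for binucleate nuclei, 28.4% for mesenchyme, 70.1% for endothelium, 58.2% for uterine epithelium, 76.1% for uterine stroma and 68.7% for the interaction. At a log2 fold change of 1 it recovered between 1.5% (mesenchyme) and 21.2% (the interaction). False calls among all calls were 14 of 127 for trophoblast, 16 of 126 for binucleate nuclei, 10 of 63 for mesenchyme, 11 of 128 for endothelium, 4 of 97 for uterine epithelium, 3 of 119 for uterine stroma and 19 of 142 for the interaction, so in 5 of the 7 fits they exceeded the nominal 5%.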

Results

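Nuclei of bovine placenta were profiled by single-nucleus RNA sequencing at 6 stages of gestation, from E60 to E280, close to term in cattle. The series asks how the cell populations of the placenta and their expression differ along gestation. The 19 deposited libraries comprised 3 at E60, 3 at E85, 2 at E110, 4 at E180, 4 at E240 and 3 at E280, while the series text speaks of fewer samples. Library totals were 24.9 to 79.4 M UMIs at E60, 35.7 to 39.9 at E85, 35.9 to 61.6 at E110, 15.6 to 45.4 at E180, 18.6 to 45.5 at E240 and 39.0 to 45.2 at E280, over 6832 to 11547 barcodes per library.

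The libraries of a stage were repeated runs of the same nuclei. In all 22 pairs of libraries within a stage, between 99.19% and 100% of the barcodes of the smaller library were also in the larger, and UMI totals of shared nuclei correlated at r of 0.9981 or more on the log10 scale. Pairs from different stages shared at most 0.4% of barcodes. The chi-square of gene counts per degree of freedom was 0.3645 to 4.174 within stages and at least 52.45 between stages. In 9 of the 22 pairs it lay below 1, so those libraries differed by less than the sampling noise. Runs were therefore averaged and each stage was counted as 1 sample, n = 6 in all, with no biological replicate of a stage.

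Clustering separated trophoblast-like nuclei, binucleate-like trophoblast (the hormone-secreting cells of the ruminant placenta), uterine epithelium-like and uterine stroma-like nuclei of the maternal side, mesenchymal stroma-like, smooth muscle or pericyte-like, endothelium-like, macrophage-like, neutrophil-like and T or NK lymphocyte-like nuclei. Uterine epithelium-like nuclei were the largest class in 4 of the 6 stages, at 35.2% of nuclei at E60, 59.8% at E85, 58.2% at E110, 70.6% at E180, 23.1% at E240 and 59.5% at E280 (means over runs). Trophoblast-like nuclei made 36.3%, 17.9%, 24.9%, 13.5% and 43.0% at E60 to E240 and 0.156% at E280. Binucleate-like nuclei made 9.0%, 6.83%, 7.89%, 5.12% and 16.7% at E60 to E240 and 0.114% at E280. In the deepest run of E280, 15 of 9746 nuclei were trophoblast-like (0.154%, exact 95% interval 0.086 to 0.254%) and 11 were binucleate-like (0.113%, 0.056 to 0.202%), against 42.95% (42.01 to 43.90%) and 15.8% (15.1 to 16.5%) at E240.

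E280 also differed from the other stages in its blood and stromal cells. Macrophage-like nuclei were 15.01% of nuclei there and between 1.03% and 1.59% in the other 5 stages, and neutrophil-like nuclei 5.90% there against at most 0.035% elsewhere. At E85 no nucleus of 6425 was neutrophil-like, which allows a share of up to 0.0467%. Uterine stroma-like nuclei were 8.90% at E280 against 0.602 to 1.51% elsewhere, endothelium-like nuclei 5.47% against 0.960 to 3.36%, and T or NK lymphocyte-like nuclei 0.798% against 0.047 to 0.323%. Mesenchymal stroma-like nuclei made 1.36% at E60, 1.23% at E85, 0.626% at E110, 0.010% at E180 (1 of 10271 nuclei, exact 95% interval up to 0.054%) and 0.276% at E240, and 0 of 9746 at E280, which allows up to 0.0308%, so a difference between E180 and E280 was not detectable. The unnamed clusters held 13.2%, 10.4%, 3.49%, 7.27%, 10.0% and 1.85% of nuclei from E60 to E280. Nuclei were sorted before loading, which can set the share of large or fragile cells.

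No class differed between the late and the early stages by the exact two-sided permutation test, which with 3 stages against 3 cannot give a p below 0.1. Mesenchymal stroma-like nuclei averaged 1.08 ± 0.394% early and 0.095 ± 0.156% late (SD, n = 3 each, exact permutation p = 0.1, adjusted p = 0.733). Macrophage-like nuclei averaged 1.25 ± 0.299% and 5.84 ± 7.94% (p = 0.5, exact permutation, n = 3 each), a difference of 4.59 percentage points that was 0.006 without E280. Trophoblast-like nuclei averaged 26.4 ± 9.33% and 18.9 ± 21.9% (p = 0.7, exact permutation, n = 3 each), and the difference of -7.48 points became 1.88 without E280. For binucleate-like nuclei the difference was -0.585 points, and 3.02 without E280.

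**Figure D1:**
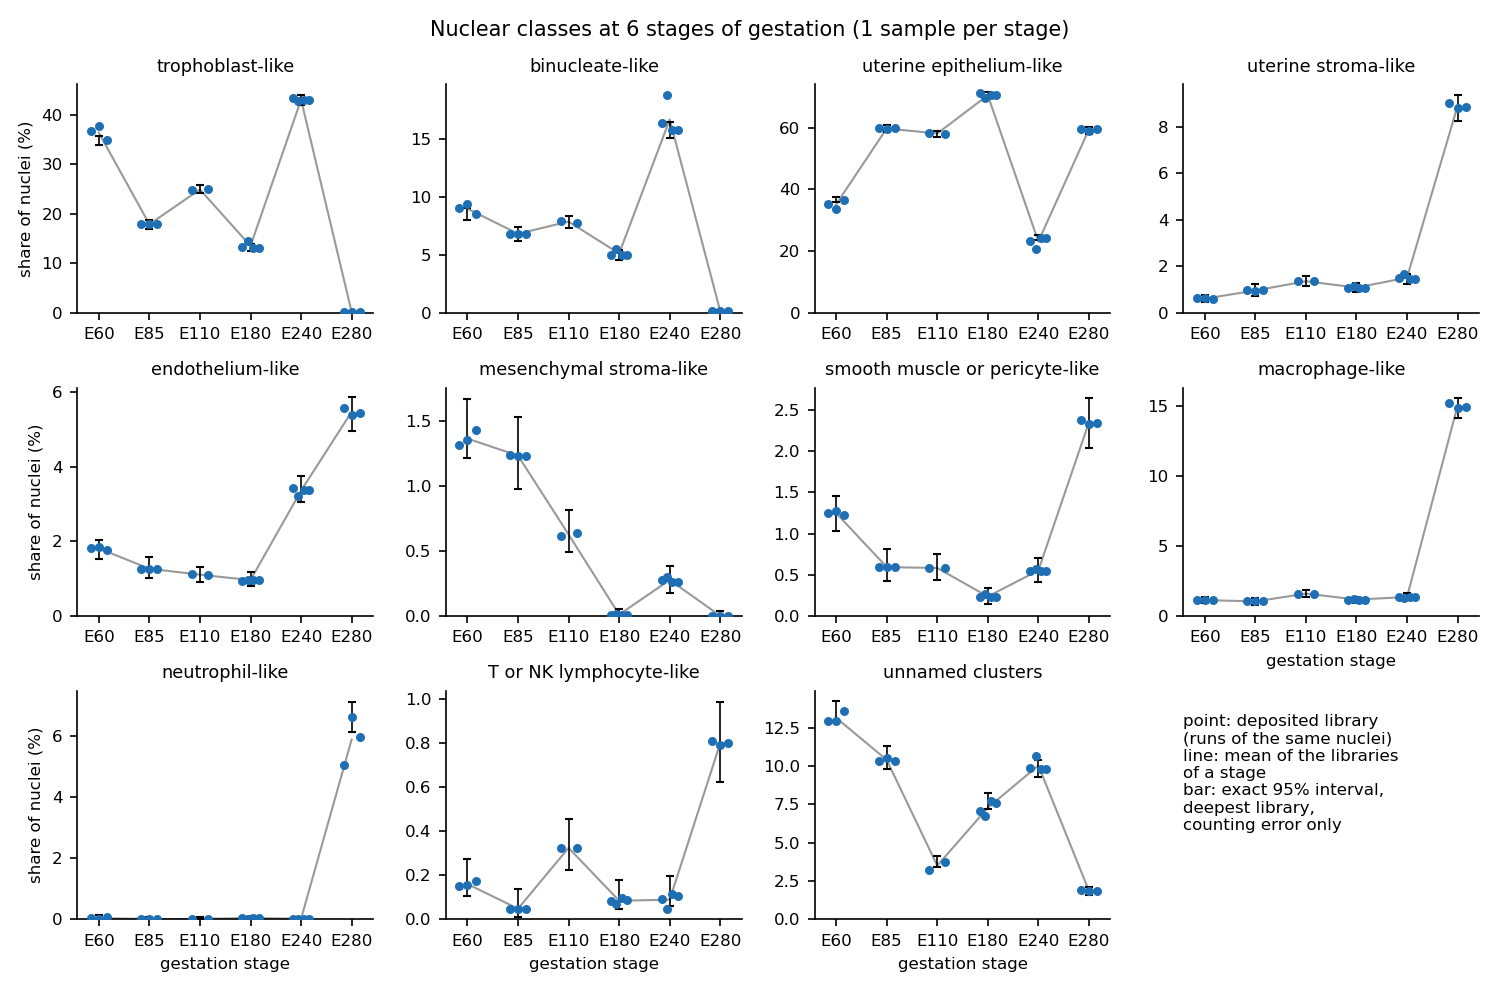
Share of nuclei (%) of each class at the 6 stages of gestation; points are single libraries, which hold the same nuclei, the line joins their means and bars are exact 95% intervals of the deepest library. Trophoblast-like nuclei made 43.0% at E240 and 0.156% at E280, and macrophage-like nuclei 15.01% at E280.

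In trophoblast-like nuclei, single transporter genes averaged higher and proliferation genes lower in the late (E180 and E240) than in the early stages (E60, E85 and E110), though no gene passed the test. SLC7A8, a transporter of neutral amino acids, averaged 174 CPM early and 377 CPM late (log2 fold change 1.11, SE 0.22), and TRPV6, the apical calcium channel of absorbing epithelia, 9.81 and 84.9 CPM (3.10, SE 0.69). The proliferation marker MKI67 averaged 47.4 and 20.4 CPM (-1.23, SE 0.25). Each of these had every late stage beyond every early stage, n = 2 and 3 samples. By edgeR none of 12181 genes passed the adjusted threshold (adjusted p = 0.302, 0.364 and 0.317 for these 3 genes), while 1190 had an unadjusted p under 0.05 and DESeq2 called 191. The groups did not overlap in 3274 genes (26.9%, where chance gives 20%). Without E180, which leaves E240 as the only late sample, edgeR called 69 genes, and 1 gene without any 1 of E60 runs 1 and 2, E85 run 2, E110 run 2, E180 runs 1 to 4 and E240 runs 1 to 3.

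Among the 14 list members with the smallest p in trophoblast-like nuclei, ACSL5, which activates fatty acids, averaged 33.6 CPM early and 126 late (1.90, SE 0.24, edgeR adjusted p = 0.170). SCARB1, the receptor for high-density lipoprotein, averaged 63.0 and 17.2 CPM (-1.87, SE 0.24, adjusted p = 0.170). The list of stress and immediate early genes did not pass, and its members went both ways. The chaperones HSP90AA1, HSPA1A and DNAJB1 did not pass singly either (adjusted p = 0.293, 0.317 and 0.293): HSP90AA1 averaged 1356 CPM early and 263 late (-2.37, SE 0.38), HSPA1A 465 and 66.8 (-2.80, SE 0.57) and DNAJB1 147 and 21.4 (-2.79, SE 0.46). The basement membrane collagens COL4A1 and COL4A2 averaged 3.65 and 2.63 CPM early and 45.7 and 23.8 late. AKR1B1, an aldo-keto reductase that can make prostaglandin F, averaged 343 and 832 CPM. TIMP2, GADD45B and SLC43A2 had log2 fold changes of 0.81, 1.86 and 1.91 and did not pass. The gene nearest the threshold, chosen after its values were seen, was RASAL1 (0.845 CPM early, 23.7 late, adjusted p = 0.0506).

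Of the fixed lists, 5 passed in trophoblast-like nuclei with camera's preset correlation. S and G2/M genes were lower late as a set (31 of 32 negative, median -0.56, adjusted p = 3.466e-13), and 6 of them were lower when adjusted over the list alone. The pregnancy-associated glycoproteins were lower (14 of 18 negative, median -0.64, adjusted p = 0.00106), with PAG11 at 180 CPM early and 59.0 late and PAG8 at 416 and 226, while PAG2, the most abundant, stood at 4134 and 4181. Genes of hypoxia and glycolysis (24 of 28 positive, median 0.35, adjusted p = 0.000377), interferon-stimulated genes (13 of 14, 0.67, adjusted p = 0.00202) and amino acid transporters (12 of 17, 0.30, adjusted p = 0.0128; 3 higher when adjusted over the list alone) were higher. With an estimated correlation none of the 5 passed: adjusted p = 0.549 with an estimated correlation for all but the interferon-stimulated genes, and adjusted p = 0.618 with an estimated correlation for those. MX1, an antiviral GTPase, averaged 19.2 and 53.7 CPM, but its stages overlapped. With the preset correlation, calls were lost without E240 for hypoxia and glycolysis (adjusted p = 0.407), interferon-stimulated genes (0.170) and amino acid transport (0.134; 0.0670 without E85, 0.0705 without E110), and without E180 for the glycoproteins (0.154).

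The other 20 lists did not pass in trophoblast-like nuclei. Steroid metabolism had a median of 0.13 (10 of 18 positive). Its members HSD3B1, which makes progesterone, averaged 1083 CPM early and 1736 late (0.68, SE 0.29), CYP11A1 192 and 271 (0.50, SE 0.21) and the oestrogen sulphotransferase SULT1E1 2237 and 3829 (0.78, SE 0.22). The aromatase CYP19A1 ranged from 9.45 CPM at E60 to 284 at E240, and PTGS2, the inducible cyclooxygenase, from 7.995 at E85 to 275 at E240. HSD3B1, CYP19A1 and SULT1E1 were among the leading genes of cluster 6, which held most trophoblast-like nuclei of E240 and few of other stages. Medians were 0.01 for the prolactin family, 0.32 for the prostaglandin and oxytocin pathway, 0.26 for glucose transport, 0.44 for lipid handling, 0.12 for iron, calcium and zinc transport, 0.08 for imprinted genes, -0.24 for endoreduplication and fusion, 0.09 for angiogenesis, 0.26 for matrix remodelling, 0.68 for antigen presentation, -0.04 for WNT, NOTCH and TGF-beta signalling, 0.29 for trophoblast transcription factors, -0.05 for the respiratory chain, -0.04 for ribosomal proteins, -0.50 for extracellular matrix, 0.07 for growth factor signalling, -0.13 for senescence and apoptosis, -0.06 for stress genes and -0.36 for haemoglobins. Median and mean differed in sign for angiogenesis (mean -0.07), growth factor signalling (-0.06) and senescence and apoptosis (0.02), and camera's direction for ribosomal proteins was up against a negative median and mean (-0.02).

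**Figure D2:**
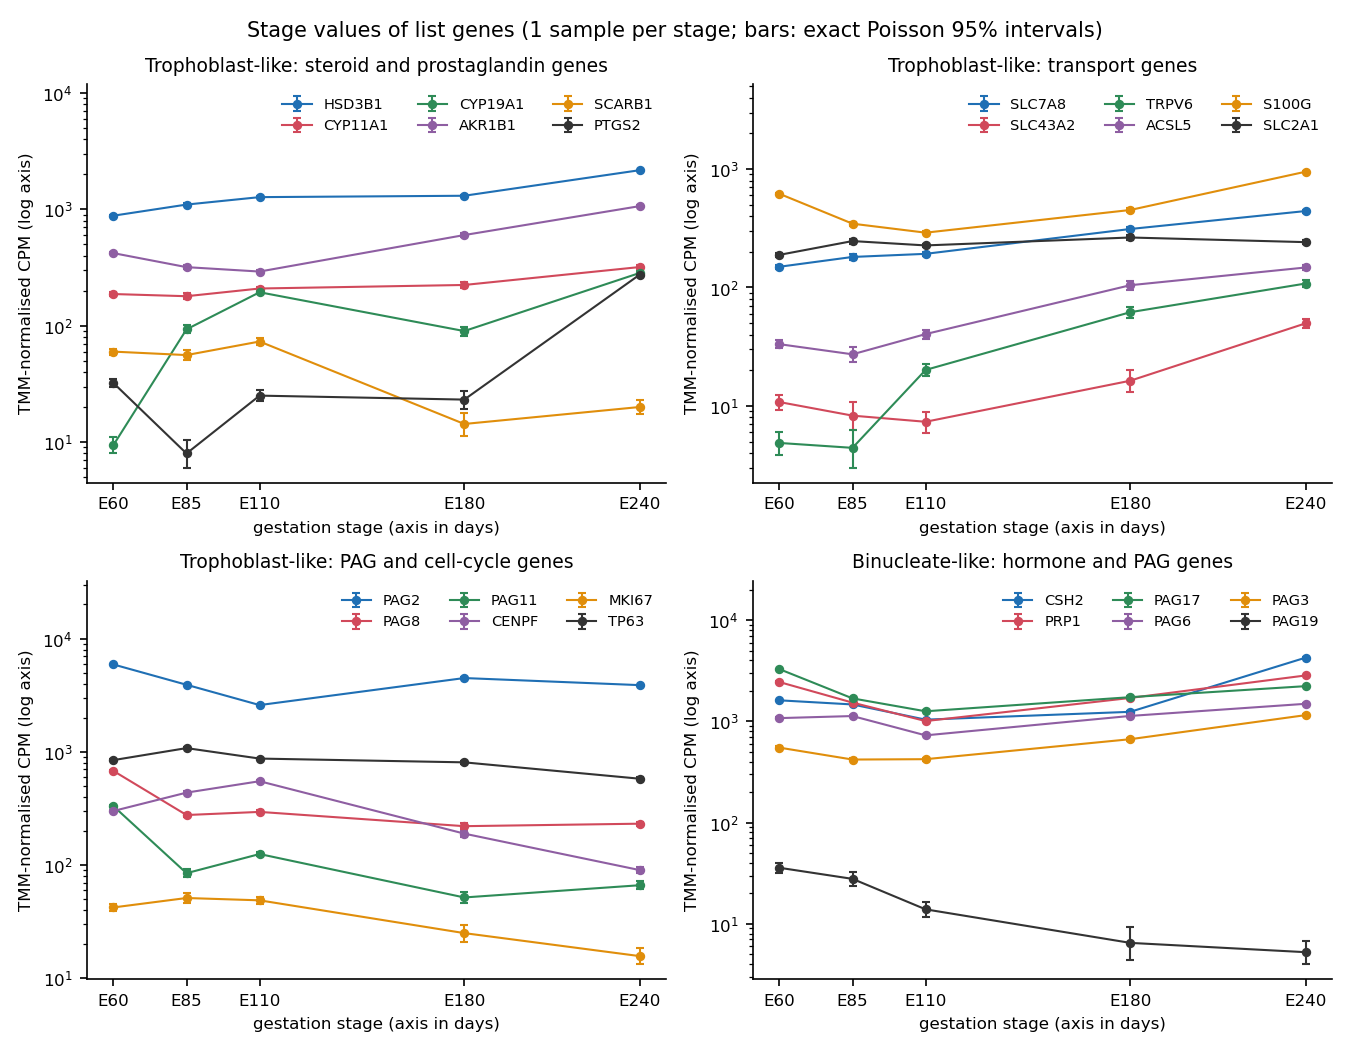
TMM-normalised CPM (log axis) of list genes from E60 to E240 (days of gestation) in trophoblast-like nuclei and, lower right, binucleate-like nuclei; points are stages, 1 sample each, and bars exact Poisson 95% intervals. In trophoblast-like nuclei TRPV6 averaged 9.81 CPM in early and 84.9 CPM in late samples.

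In binucleate-like nuclei the transcripts of the secreted products did not pass the test in either direction, and the errors of CSH2, PRP1 and PAG17 were wide. Placental lactogen CSH2 averaged 1376 CPM early and 2757 late (1.00, SE 0.49), PRP1 1664 and 2276 (0.45, SE 0.40), PAG17 2078 and 1984 (-0.07, SE 0.41) and PAG4 404 and 385 (-0.07, SE 0.17), n = 3 and 2 samples. PAPPA2, a protease that frees insulin-like growth factors from their binding proteins, averaged 22.5 and 80.0 CPM (1.82, SE 0.32), and the imprinted growth inhibitor GRB10 96.2 and 45.3 (-1.09, SE 0.20). FLT1, a receptor for vascular endothelial growth factor, averaged 495 and 804 CPM (0.70, SE 0.17). Cluster 18 held 760 of the binucleate-like nuclei of E240 and few of earlier stages, while cluster 15 held 144 to 357 of each stage from E60 to E180 and 10 of E240. By edgeR none of 11374 genes passed (adjusted p = 0.624 for PAPPA2 and GRB10, 0.644 for FLT1), with 837 at an unadjusted p under 0.05 and 59 called by DESeq2. The groups did not overlap in 2687 genes (23.6%, chance 20%).

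Within this class PAG3 averaged 465 CPM early and 911 late and PAG19 25.8 and 5.86, neither passing (adjusted p = 0.649 and 0.642), while 2 PAG genes were lower when adjusted over the list alone. The zinc and iron importer SLC39A8 averaged 29.0 and 76.7 CPM, the hexokinase HK2 10.5 and 23.9, B2M 44.5 and 86.1, GADD45G 64.7 and 102 and ERBB3 84.2 and 127. FGFR2 averaged 412 and 279 CPM. The chaperones HSP90AA1 (893 and 314 CPM), HSPH1 (53.0 and 16.96) and DNAJB1 (48.6 and 7.59) had the same order as in trophoblast-like nuclei. With camera's preset correlation, hypoxia and glycolysis (23 of 28 positive, median 0.45, adjusted p = 6.744e-05), amino acid transport (12 of 14, 0.27, adjusted p = 0.0153) and ribosomal proteins (28 of 31, 0.24, adjusted p = 0.0153) were higher late and extracellular matrix lower (16 of 20 negative, median -0.40, adjusted p = 0.0153), with LAMB1 at 17.6 and 3.55 CPM. With an estimated correlation these gave adjusted p = 0.901 with an estimated correlation for ribosomal proteins and adjusted p = 0.693 with an estimated correlation for the other 3. Without E240 all 4 calls were lost (adjusted p = 0.495 for hypoxia and glycolysis, 0.349 for amino acid transport, 0.898 for ribosomal proteins, 0.0828 for extracellular matrix). Without E110 the ribosomal list turned to lower (0.539) and the matrix call was lost (0.117), as it was without E60 run 3 (0.111) or E110 run 2 (0.0958).

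The late against early difference of cell cycle genes seen in other trophoblast was smaller in binucleate-like nuclei. S and G2/M genes had medians of -0.56 in trophoblast-like and -0.13 in binucleate-like nuclei (difference positive in 27 of 32, median difference 0.53, camera adjusted p = 1.703e-14, adjusted p = 0.402 with an estimated correlation), and 15 of the 32 were higher when adjusted over the list alone. MKI67 differed by 1.15 (SE 0.20), CENPF by 1.07 (SE 0.19) and GINS2 by 1.29 (SE 0.23) on the log2 scale, from 3 early and 2 late samples. COL4A1 had the opposite difference of -4.45 (SE 0.43, edgeR adjusted p = 0.0941), as had COL4A2 (-3.98), TRPV6 (-2.38), PAG11 (-2.71), AKR1B1 (-1.60), GADD45G (-1.55), ACSL5 (-1.22) and ACSL3 (-1.04). SLC39A8 (2.07), CD36 (1.64) and PAG4 (1.15) differed upwards. By edgeR none of 12719 genes passed, 1330 had an unadjusted p under 0.05 and DESeq2 called 73. Without E180 edgeR called 83.

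Another 5 lists passed for this difference with the preset correlation. Pregnancy-associated glycoproteins (15 of 19 positive, median 0.55, adjusted p = 0.0407, adjusted p = 0.611 with an estimated correlation) and ribosomal proteins (30 of 31, 0.22, adjusted p = 0.000574, adjusted p = 0.611 with an estimated correlation) were relatively higher in binucleate-like nuclei. Lipid handling (12 of 17 negative, median -0.89, adjusted p = 0.0304), imprinted genes (12 of 16 negative, -0.23, adjusted p = 0.0379) and extracellular matrix (14 of 27 negative, median -0.05, mean -0.56, adjusted p = 0.0304) were relatively lower, each with adjusted p = 0.402 with an estimated correlation. For the glycoproteins 1 member was higher and 3 lower when adjusted over the list alone, PAG4 and PAG11 being the examples with the smallest p. Leaving out E60 run 3 (adjusted p = 0.0796, 0.0675, 0.0796 and 0.0796), E110 (0.225, 0.0605, 0.0930 and 0.0669), E180 (0.0814, 0.0801, 0.0550 and 0.0550) or E240 (0.195, 0.242, 0.242 and 0.393) ended the calls of the glycoproteins, lipid handling, imprinted genes and extracellular matrix, in this order. The glycoprotein call also ended without E85 (0.0974), E85 run 2 (0.0616), E240 run 1 (0.0608) or run 4 (0.0511), imprinted genes without E60 (0.0825) or E180 run 3 (0.0527), and extracellular matrix without E60 (0.0825).

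In mesenchymal stroma-like nuclei 4 genes were called higher at E240, the only late stage with at least 20 such nuclei (28 nuclei, against 155, 79 and 65 at E60, E85 and E110). This lone late sample was assumed to vary like the early ones, the stage cannot be told from the sample, and 10 of the 63 calls of this fit in simulated data were false. GHR, the growth hormone receptor, averaged 273 CPM early and 2466 at E240 (log2 fold change 3.19, SE 0.35, edgeR adjusted p = 0.0472). PTX3, a secreted pattern recognition protein, had 23.0 and 546 CPM (4.59, SE 0.43, adjusted p = 0.0316). VEGFC, a lymphangiogenic growth factor, had 3.65 and 546 CPM (7.24, SE 0.65, adjusted p = 0.0316) and CFH, complement factor H, 2.12 and 476 CPM (7.08, SE 0.71, adjusted p = 0.0347). Early counts were few: VEGFC had 2 early and 31 late counts (count ratio 188, interval 47.9 to 1624), CFH 2 and 27 (164, 41.2 to 1423), PTX3 15 and 31 (25.1, 13.1 to 50) and GHR 177 and 140 (9.60, 7.60 to 12.1). Leaving out a library or a stage moved the log2 fold change of CFH between 6.62 and 9.23 and that of VEGFC between 6.50 and 8.04. These 4 were all of the calls among 5301 genes by edgeR, 1 late against 3 early samples, with 622 genes at an unadjusted p under 0.05 and 17 called by DESeq2; 3859 genes did not overlap (72.8%, chance 50%). The GHR call was lost with doublets kept (adjusted p = 0.0562), with at least 1000 genes per nucleus (0.0738), without E60 run 1 (0.0699) and without E240 run 3 (0.0551) or 4 (0.0584), and the CFH call without E240 run 3 (0.0545) or 4 (0.0584). The number of calls ranged from 2 (without E240 run 3 or 4) through 7 (E85 run 1) and 13 (E60 run 3, E110 run 1) to 16, 18 and 89 without E85, E60 or E110.

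None of the other listed members passed in these nuclei. HIF1A averaged 269 CPM early and 951 at E240, PDGFD 160 and 564, GRB10 250 and 863, the transferrin receptor TFRC 41.4 and 247, MMP16 214 and 1867, TNXB 29.9 and 229, COL6A3 199 and 528, SLC7A8 12.6 and 176 and SLC43A2 21.4 and 194. RSPO3, a WNT enhancer, averaged 479 and 141 CPM, PAG2 399 and 35.2, and the metalloprotease ADAMTS20 327 early with no count at E240. PAG2 is a trophoblast marker, and over all stages it also stood at 306 raw CPM in endothelium cluster 19 and 513 in smooth muscle cluster 34. Angiogenesis (8 of 11 positive, median 0.97, adjusted p = 9.563e-05), hypoxia and glycolysis (13 of 17, 0.97, adjusted p = 0.00392), iron, calcium and zinc transport (6 of 9, 0.77, adjusted p = 0.0149), interferon-stimulated genes (5 of 5, 1.09, adjusted p = 0.000993) and ribosomal proteins (29 of 31, 0.57, adjusted p = 0.000993) were higher with the preset correlation. So were the prolactin family (3 of 4, median 1.25 but mean near 0 at -0.001) and matrix remodelling (10 of 14, median 1.38, mean -0.06). GHR, called above, is 1 of the 4 prolactin members, beside CSH2 at 1.14, PRP1 at 1.35 and PRP2 at -5.68. CSH2 and PRP1 are transcripts of binucleate cells, which made 16.7% of nuclei at E240. There CSH2 and PRP1 stood at 136 and 92.0 raw CPM in endothelium-like nuclei. In smooth muscle or pericyte-like nuclei they stood at 214 and 170. A mesenchymal source of either is therefore not established. S and G2/M genes (13 of 14 negative, -1.53, adjusted p = 0.00709) and the prostaglandin and oxytocin pathway (4 of 4 negative, -1.60, adjusted p = 0.0238) were lower. All 9 calls were lost with an estimated correlation: adjusted p = 0.585 with an estimated correlation for S and G2/M, adjusted p = 0.599 with an estimated correlation for ribosomal proteins and adjusted p = 0.364 with an estimated correlation for the other 7. Without E60 the S and G2/M call was lost with the preset correlation as well (adjusted p = 0.207).

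In endothelium-like nuclei cell cycle transcripts averaged lower in the late stages, with part of the early level left at E180. All 17 measured S and G2/M genes were lower late (median -2.21, camera adjusted p = 3.033e-16, adjusted p = 0.702 with an estimated correlation). ANLN averaged 54.0 CPM early and 9.34 late, with 22.7 at E180 (log2 fold change -3.13, SE 0.71), and KIF20B 137 and 35.5, with 75.6 at E180 (-2.21, SE 0.62), n = 3 and 3 samples. ADAM12, a membrane metalloprotease, had the smallest p, with 221 and 36.0 CPM (-2.67, SE 0.25, edgeR adjusted p = 0.0612). Genes of hypoxia and glycolysis were higher late (17 of 18 positive, median 0.92, adjusted p = 7.382e-05, adjusted p = 0.702 with an estimated correlation), with PGK1 at 55.6 and 182 CPM and PFKFB3 at 21.0 and 75.7.

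No single gene passed in this class. The stress-induced genes DDIT4 (13.4 and 115 CPM), CDKN1A (16.4 and 119) and GADD45A (41.6 and 94.5) and the metalloprotease ADAMTS9 (666 and 1660) averaged higher late. ADAMTS6 (547 and 163), the iron exporter SLC40A1 (122 and 50.6), CD74 (76.2 and 28.0), LMNB1 (79.6 and 26.5) and NRP1 (1884 and 892) averaged lower. Imprinted genes were lower as a list (11 of 13 negative, median -0.59, adjusted p = 0.00488, adjusted p = 0.702 with an estimated correlation), with PEG10 at 72.3 and 22.2 CPM, and so were 4 of 4 measured PAG genes (-0.97, adjusted p = 0.0267, adjusted p = 0.702 with an estimated correlation), which trophoblast and binucleate cells express; these classes made only 0.156% and 0.114% of nuclei at E280. Ribosomal proteins were higher (31 of 31, 0.33, adjusted p = 0.0360, adjusted p = 0.909 with an estimated correlation), but the list turned to lower without E110 (adjusted p = 0.933) or E280 (0.598) and the call was lost without E85 (0.134). The imprinted call was lost without E180 (0.0781) or E280 (0.367), and the PAG call without E280 (0.206) or E60 run 3 (0.115). By edgeR none of 6408 genes passed, with 552 at an unadjusted p under 0.05 and 40 called by DESeq2, and 898 genes did not overlap (14%, chance 10%). Without E180 edgeR called 47, without E85 run 1 or E110 run 2 it called 2, and without E180 run 1 or 4 it called 1. Most endothelium-like nuclei of E280 came from cluster 21 (509 of its 673 nuclei) and those of earlier stages from cluster 19, which DLK1 helped to define.

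In uterine epithelium-like nuclei, the transporters SLCO2A1 and SLC7A8 and the glycolysis gene PFKFB3 averaged higher late and were highest at E280. The prostaglandin and oxytocin list (median 0.34) and the amino acid transport list (0.28) did not pass. The hypoxia and glycolysis list leaned lower at E280 than at E240 (18 of 28 negative, median log2 ratio -0.24, percentile 7.23 among random lists). The nuclei compared came mostly from clusters 0 and 5 at E60, 0, 5, 2 and 4 at E85, 4 (3725 nuclei) and 10 (1322) at E110, 0, 2 and 5 at E180 and E240, and 3 (4950) and 24 (566) at E280. SLCO2A1, the prostaglandin transporter, was higher at each later stage, from 11.4 CPM at E60 to 350 at E280 (20.8 early, 178 late, log2 fold change 3.09, SE 0.81), SLC7A8 had 17.2 and 187 CPM (3.44, SE 0.95) and PFKFB3, which drives glycolysis, 24.1 and 238 (3.30, SE 0.77), n = 3 and 3 samples. DDIT4 averaged 24.8 and 66.3 CPM (1.42, SE 0.23, edgeR adjusted p = 0.408, the smallest among listed genes). Stress and immediate early genes were higher late as a list (20 of 24 positive, median 0.59, camera adjusted p = 0.000358, adjusted p = 0.763 with an estimated correlation), with DUSP1 at 6.06 and 62.4 CPM; without E280 the list's adjusted p was 0.0737.

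SERPINE1, the inhibitor of plasminogen activators, averaged 6.25 CPM early and 55.7 late in this class, TFAP2A 15.1 and 55.0, ADAMTS12 6.32 and 21.7, FDXR 18.9 and 35.9 and FTH1 364 and 696. SLC8A1 averaged 44.4 and 9.42 CPM, DKK1 46.6 and 16.2 and EFNB2 38.7 and 17.01. PAG10 was at 7.52 and 214 CPM, but its stages overlapped and E280 alone reached 585. The PAG list as a whole was lower (14 of 18 negative, median -0.64, adjusted p = 0.00559, adjusted p = 0.763 with an estimated correlation), where trophoblast-like and binucleate-like nuclei, which express these genes, made 0.156% and 0.114% of nuclei at E280. S and G2/M genes were lower too (28 of 32, -0.56, adjusted p = 1.872e-06, adjusted p = 0.763 with an estimated correlation), with CENPE at 660 and 326 CPM. Both calls were lost without E280 (adjusted p = 0.232 and 0.0542), and the PAG call without E60 (0.0554). Mitosis genes also led clusters 5 and 10 of this class. By edgeR none of 13229 genes passed, 1120 had an unadjusted p under 0.05 and DESeq2 called 295; 2069 genes did not overlap (15.6%, chance 10%). Without E280 edgeR called 4.

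In uterine stroma-like nuclei ADAM12 was again the listed gene with the smallest p, at 754 CPM early and 131 late (log2 fold change -2.51, SE 0.26, edgeR adjusted p = 0.0643, n = 3 and 3 samples). IGF1, insulin-like growth factor 1, ranged from 74.0 to 500 CPM in the early and from 20.1 to 49.7 in the late samples (-2.96, SE 0.67). ADM, the vasodilator adrenomedullin, averaged 182 and 794 CPM (2.13, SE 0.45) and PLAU, the urokinase plasminogen activator, 11.4 and 109 (3.01, SE 0.56). Angiogenesis genes (12 of 14 positive, median 1.06, camera adjusted p = 1.489e-05, adjusted p = 0.211 with an estimated correlation) and genes of hypoxia and glycolysis (16 of 18, 0.65, adjusted p = 4.145e-05, adjusted p = 0.582 with an estimated correlation) were higher late, HIF1A being at 56.4 and 166 CPM.

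Matrix remodelling genes were higher as a list in this class (9 of 15 positive, median 0.40, adjusted p = 0.0258, adjusted p = 0.582 with an estimated correlation), and 4 were higher when adjusted over the list alone, MMP14 among the examples (77.2 and 210 CPM). Ribosomal proteins were higher (31 of 31, 0.45, adjusted p = 5.389e-05, adjusted p = 0.657 with an estimated correlation). The list of endoreduplication and fusion was lower (5 of 6 negative, median -0.40, adjusted p = 0.00296, adjusted p = 0.271 with an estimated correlation), with ADAM12 as its strongest member. The remodelling call was lost without E60 run 1 (adjusted p = 0.163) or 2 (0.172), E180 run 3 (0.105) or 4 (0.108), E85 (0.0571) or E240 (0.192), the ribosomal call without E110 (0.435) or E240 (0.0512), and the endoreduplication call without E60 (0.0733). FTL (54.7 and 189 CPM), PLIN2 (48.7 and 134), SLC38A1 (88.3 and 227), ACSL4 (78.6 and 398), INHBA (11.02 and 63.5) and WNT2 (52.8 and 170) averaged higher late, COL4A5 (45.0 and 4.996) and NOTCH3 (35.2 and 13.3) lower. By edgeR none of 6407 genes passed, 524 had an unadjusted p under 0.05 and DESeq2 called 87; 845 genes did not overlap (13.2%, chance 10%). Without E180 edgeR called 15, without E180 run 4 it called 4, without E110 run 2 it called 3, without E180 run 3 it called 2, and without E85 or E280 it called 1. Cluster 14 held most of this class at E280 and cluster 30 most of it before.

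**Figure D3:**
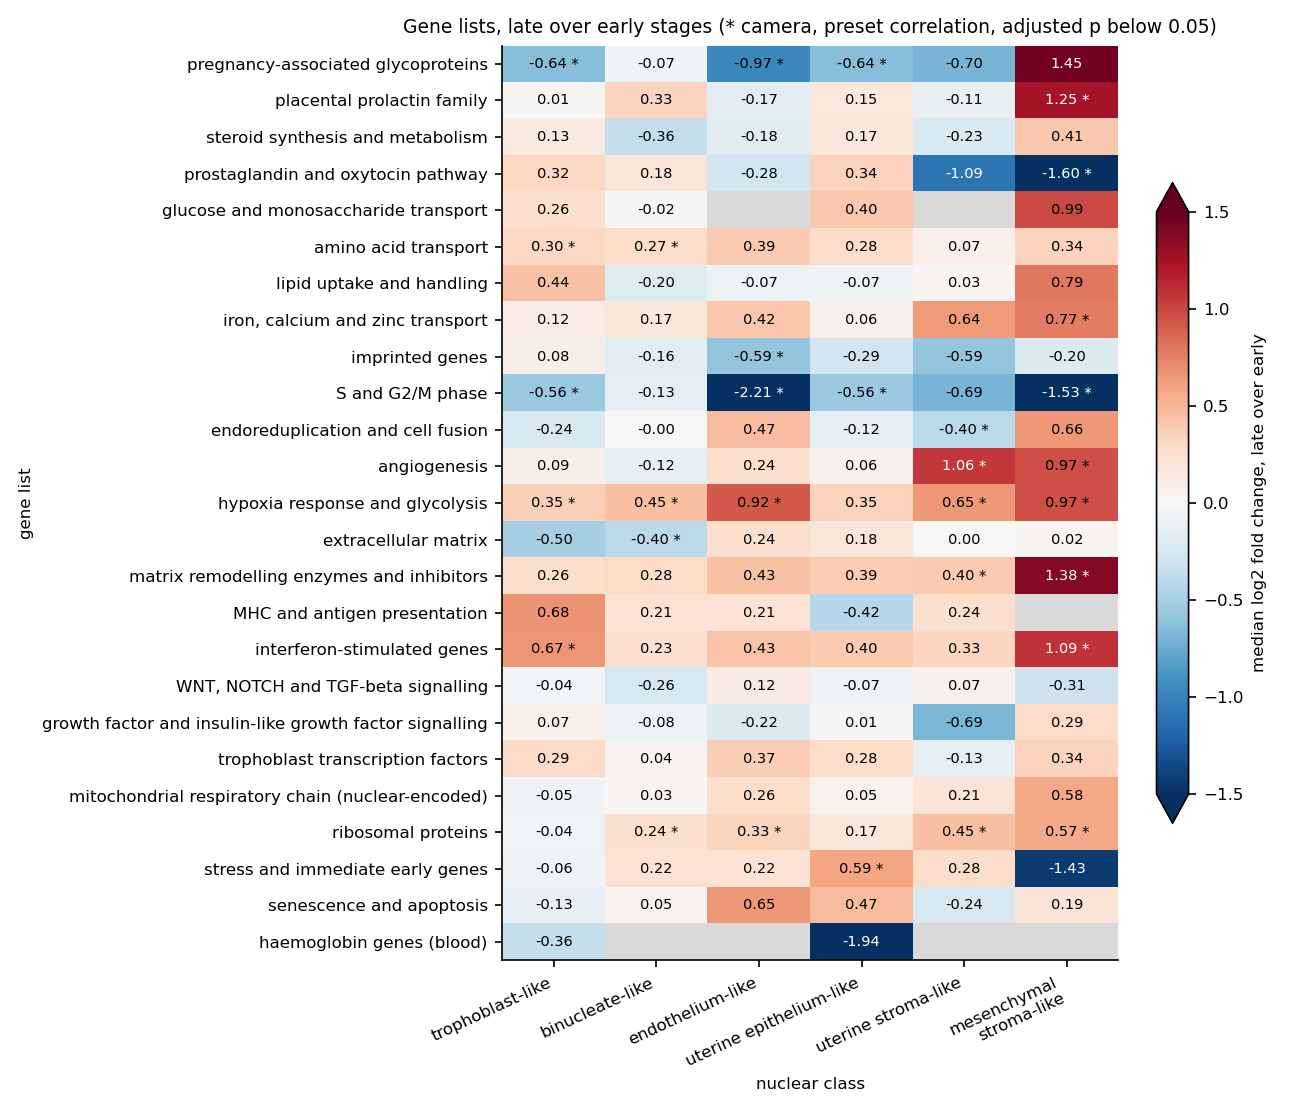
Median log2 fold change, late over early stages, of the 25 gene lists (vertical axis) in 6 nuclear classes (horizontal axis); an asterisk marks camera's adjusted p under the threshold with the preset correlation, and grey a list with too few tested members. S and G2/M genes had medians of -0.56, -2.21 and -0.56 in trophoblast-like, endothelium-like and uterine epithelium-like nuclei.

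E280 was set beside E240, the last step before term, as 1 sample against 1, so no test was run. Gene ratios are given with their 95% counting interval and list medians with their place among 10000 random lists. In each class the stages came mostly from different clusters, so a change within a population cannot be told from a change of population. In uterine epithelium-like nuclei (mostly clusters 0, 2 and 5 at E240, 3 and 24 at E280) the acute phase gene SAA3 stood at 1.61 CPM at E240 and 240 at E280 (log2 ratio 7.12, 6.18 to 8.54) and the iron reductase STEAP4 at 5.05 and 327 (5.99, 5.42 to 6.69). PTHLH, the parathyroid hormone-like hormone, stood at 66.8 and 0.612 CPM (-6.72, -7.66 to -6.00). SULT1E1 stood at 214 and 2.45 CPM (-6.43, -6.86 to -6.06), but over E60 to E240 it was at 136 CPM in these nuclei, below the median of 4 other classes (158 CPM), and at 2700 CPM in trophoblast-like nuclei, which made 43.0% of nuclei at E240 and 0.156% at E280. S100A9, S100A12 and TGM3, leading genes of neutrophil-like cluster 22, were also among the largest rises. S100A9 had a log2 ratio of 5.87 to 6.01 with single libraries left out. In the deepest run of E280 it stood at 116 raw CPM in uterine epithelium-like nuclei and at 16810 in cluster 22. An epithelial source of these genes is therefore not established. Random lists were matched on size and expression alone, so a place among them covers neither correlation between genes nor spread between samples. All 32 S and G2/M genes were at or below their E240 level (median -2.01), a median below those of all random lists. The medians of imprinted genes (-2.05) and ribosomal proteins (31 of 31 negative, -0.89) were below all of them too, and endoreduplication and fusion genes (-1.28) and the respiratory chain (23 of 24 negative, -0.82) stood at percentile 0.01. At the other end stood matrix remodelling (1.014, percentile 99.75), extracellular matrix (0.59, 99.91), stress genes (0.52, 99.91) and senescence and apoptosis (0.58, 99.86). The PAG list, of genes that trophoblast and binucleate cells express, had a median of -2.18, with 16 of 18 negative, and medians of -3.46 and -2.93 in uterine stroma-like and endothelium-like nuclei.

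In endothelium-like nuclei (mostly cluster 19 at E240 and 21 at E280) the adhesion receptor SELP, which binds leukocytes, stood at 60.7 and 1123 CPM (log2 ratio 4.19, 3.72 to 4.75), SERPINE1 at 40.4 and 1921 (5.54, 4.97 to 6.25) and the chemokine GRO1 at 7.35 and 604 (6.19, 5.002 to 8.24). GRO1 stood at 5570 CPM in neutrophil-like cluster 22 of E280, at 1241 and 2474 in macrophage-like clusters 13 and 28 and at 300 in uterine stroma-like nuclei (raw CPM, deepest run). Neutrophil-like nuclei made 5.90% of E280 against at most 0.035% elsewhere, so an endothelial source of GRO1 is not established. DLK1, an imprinted Notch ligand, stood at 5088 and 36.1 CPM (-7.13, -7.47 to -6.83) and SLC16A10, an amino acid transporter, at 4852 and 54.1 (-6.48, -6.76 to -6.23). DLK1 was among the leading genes of cluster 19, so its ratio follows in part from the cluster that each stage held. Interferon-stimulated genes were higher at E280 (23 of 24 positive, median 1.97, above every random list). Lipid handling (12 of 16 positive, 1.20), senescence and apoptosis (1.17), ribosomal proteins (31 of 31 positive, 0.95) and hypoxia and glycolysis (0.92) were above every random list as well, and imprinted genes below every one (13 of 16 negative, -2.75). The lipid handling genes did not all rise: CD36 was among the largest falls of this class. Its log2 ratio was -6.62 to -6.52 with single libraries left out. In uterine stroma-like nuclei (mostly cluster 30 at E240 and 14 at E280) PAPPA, a protease of insulin-like growth factor binding proteins, stood at 60.3 and 986 CPM (4.00, 3.43 to 4.71), and CA8 had a log2 ratio of 5.22 (4.03 to 7.27). PAG2 had a ratio of -6.81 there (-8.27 to -5.79, 209 and 1.74 CPM), and SULT1E1 of -7.19 (-9.27 to -5.91, 162 and 0.995 CPM), levels far below those of trophoblast cluster 6 (6194 and 6396 raw CPM), whose class was nearly lost at E280. Some lists went the other way than in endothelium-like nuclei. In uterine stroma-like nuclei interferon-stimulated genes (14 of 23 negative, median -0.55, percentile 0.73) and extracellular matrix (27 of 35 negative, -0.64, percentile 0.1) stood low. Ribosomal proteins were negative in 31 of 31 (-0.69, below every random list). Imprinted genes were lower in both classes (12 of 18 negative in uterine stroma-like nuclei, -0.72, percentile 0.5).

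Transcripts of binucleate cells were also counted in other classes. Binucleate-like nuclei carried 135, 157, 106, 112, 138 and 131 UMIs of their marker genes per nucleus from E60 to E280. Uterine epithelium-like nuclei carried 4.31, 5.58, 3.06, 4.18, 4.26 and 4.51, and the highest of 4 other classes (uterine stroma, endothelium, macrophage, smooth muscle) 1.65, 5.11, 3.05, 3.74, 1.67 and 0.869. The uterine epithelium thus lay 2.56 to 5.19 times above these classes at E60, E240 and E280, and at 1.00 to 1.12 times their highest level at E85, E110 and E180. The marker set is not particular to binucleate cells, since it includes SULT1E1. Over E60 to E240 this gene stood at 2939 raw CPM in binucleate-like and 2700 in trophoblast-like nuclei. In uterine epithelium-like nuclei it stood at 136, against a median of 158 in the 4 other classes.

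**Figure D4:**
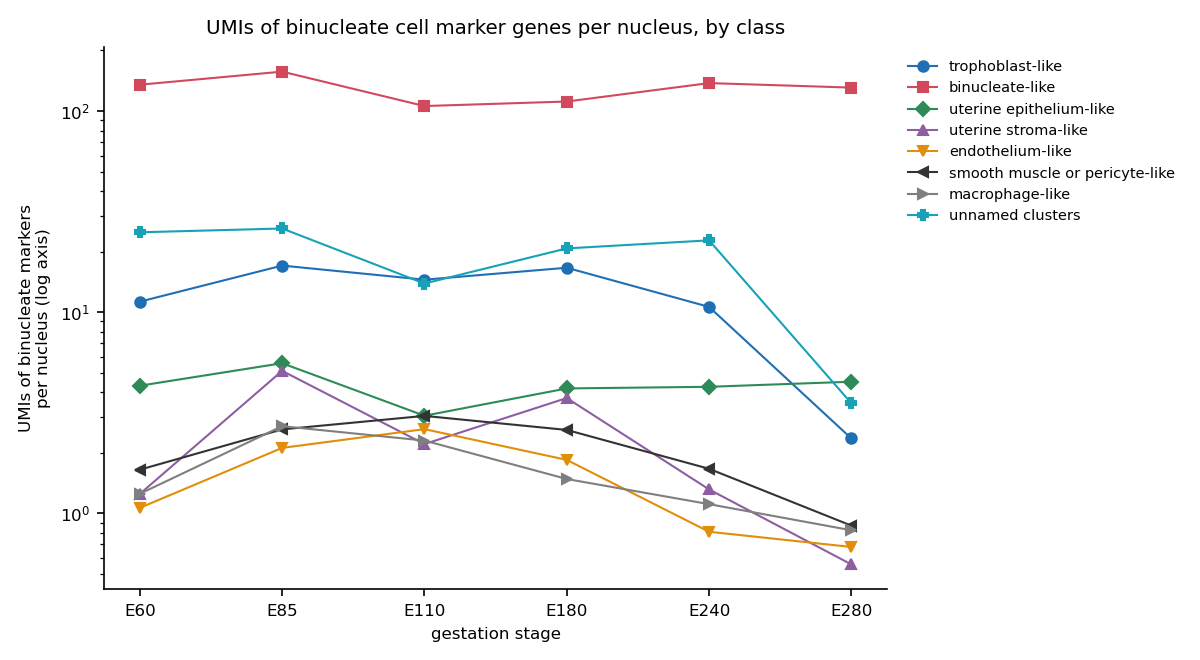
UMIs of binucleate marker genes per nucleus (log axis) at each stage of gestation; points are means over the runs of a stage, by nuclear class. Uterine epithelium-like nuclei carried 4.51 at E280, when 0.869 was the highest of uterine stroma, endothelium, macrophage and smooth muscle. The markers include SULT1E1, which trophoblast-like nuclei carried as well.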

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

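Alternatives that left out a stage, took the deepest run alone or counted every library with 2 periods as the only term were added after the data were seen. Counting every library as its own replicate treats repeated runs of the same nuclei as independent samples. In the 6 classes this fit also had a mean per stage, so its spread was that between runs. Its large counts follow from this construction: 9122 genes for trophoblast, 7740 for binucleate nuclei, 2423 for mesenchyme, 3625 for endothelium, 11246 for uterine epithelium, 3473 for uterine stroma and 4041 for the interaction. With 2 periods as the only term these were 4482, 3332, 1598, 1310, 3937 and 1172 in the 6 classes, and with the replicate number as a block 8668, 7327, 1929, 3441, 11055 and 3289. Libraries of different stages with the same number shared some of their deviations from the stage means: over 9507 genes, 41 such pairs correlated at a median r of 0.164 (26 over 0.1, range -0.274 to 0.57) against -0.05 for 108 other pairs, and the same number was the best match in 49 of 82 combinations of a library and another stage. Deviations cancel within a stage, so the other pairs are no independent baseline. Depth was not held equal either: E60 run 3 correlated at 0.57 with E180 run 3 and at 0.575 with E180 run 4. A shared number thus cannot be told from shared depth. DESeq2 called 191, 59, 17, 40, 295, 87 and 73 genes in the same order, ending with the interaction, and the cause was not tested. Without the filter on low counts, edgeR called 11 for trophoblast, 194 for mesenchyme, 14 for endothelium, 23 for stroma and 4 for the interaction. The trend on the day of gestation gave 18 for trophoblast, 11 for mesenchyme, 34 for endothelium, 1 for uterine epithelium and 14 for stroma. Summed runs gave 94 for mesenchyme, the deepest run 17 for mesenchyme, 2 for endothelium and 3 for stroma, at least 1000 genes per nucleus 2 for endothelium and 3 for stroma, and doublets kept 1 for the interaction; the cause was not tested. Leaving out a library or a stage gave 0 to 69 calls for trophoblast, 2 to 89 for mesenchyme, 0 to 47 for endothelium, 0 to 4 for uterine epithelium, 0 to 15 for stroma and 0 to 83 for the interaction, and 0 throughout for binucleate nuclei.

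Shares of mesenchymal nuclei passed the test with every library as a replicate (-1.027 points, adjusted p = 0.0001455, 1 class called) and with the replicate block (-1.056, adjusted p = 0.00275, 1 class). Differences that changed sign were 0.374 (at least 1000 genes) and 0.068 (every library) for binucleate nuclei, -1.679 (doublets kept), -0.346 (at most 1% mitochondrial UMIs), -10.799 (centring) and -0.02 (logit scale) for uterine epithelium, whose reported difference was 0.003, -0.11 for smooth muscle (logit scale) and 8.623 for unnamed nuclei (centring); the cause was not tested. Leaving out a library or stage gave -0.091 to 0.267 for T or NK lymphocytes, -5.289 to 3.02 for binucleate nuclei, -9.762 to 13.98 for uterine epithelium, -0.414 to 0.644 for smooth muscle and -19.55 to 1.882 for trophoblast. Of the gene lists, 0 passed in any comparison with an estimated correlation, and with fry 1 passed in mesenchyme and 0 elsewhere. Summed runs gave 8 lists for endothelium and 7 for uterine epithelium, the replicate block 8 and 5, and every library as a replicate 5 for uterine epithelium and 2 for the interaction. Leaving out a library or a stage gave 3 to 6 lists for trophoblast, 2 to 9 for binucleate nuclei, 9 to 14 for mesenchyme, 3 to 7 for endothelium, 3 to 7 for uterine epithelium, 4 to 9 for stroma and 2 to 8 for the interaction. The ribosomal list had adjusted p between 6.054e-05 and 0.8983 for binucleate nuclei, lower without E110 (0.5391), and between 4.986e-09 and 0.9331 for endothelium, lower without E110 (0.9331) or E280 (0.5976). Over all alternatives, named genes kept direction and side of the threshold in 3134 values, passed in 383 more and were lost in 7, and gene lists kept both in 985, were lost in 144 and changed direction in 3. These totals pool fits that counted runs as replicates with fits that left out 1 of several runs of the same nuclei. They therefore say little about the spread between samples. Of the ratios of E280 over E240, 472 moved by less than their counting interval and 8 by more. A fit of the libraries of E280 and E240 alone, and alternatives to a test of any difference over the 6 stages in edgeR and DESeq2, were not run, because 1 sample per stage leaves no residual degrees of freedom. With at least 100 nuclei per class, mesenchyme gave no value.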

Other observations

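The macrophage-like nuclei of E280 (clusters 13 and 28, with 990 and 438 nuclei of that stage) differed from those of the 5 earlier stages (mostly cluster 23) in the transcripts that follow, here as raw CPM with 1 sample per stage and no test. CXCL8, the chemokine that draws neutrophils, stood at 1.32, 0, 5.46, 116, 80.3 and 3725 CPM from E60 to E280, CCL2 at 101, 7.06, 98.2, 45.2, 58.6 and 597, and the scavenger receptor CD36 at 88.2, 67.1, 98.2, 280, 81.4 and 862. IL6 and PTGS2 stood at no more than 1.09 and 2.17 CPM before E280 and at 111 and 195 there, but IL6 stood at 84.6 CPM in uterine epithelium-like and 91.8 in endothelium-like nuclei of E280 as well. PTGS2 stood at 235 CPM in neutrophil-like cluster 22 and 158 in uterine stroma-like nuclei of E280. It stood at 11.3 in uterine epithelium-like and 4.45 in endothelium-like nuclei. Neutrophil-like nuclei made 5.90% at E280, and ADGRE1, TGM3, PTX3, ARHGAP15 and IL1RN led both their cluster 22 and macrophage cluster 28. In the deepest run of E280 CXCL8 stood at 14050 CPM in cluster 22, 6663 in cluster 28, 2292 in cluster 13, 492 in endothelium-like and 170 in uterine epithelium-like nuclei, and S100A9 at 16810, 2056, 367, 208 and 116. SLC40A1, the iron exporter, went the other way, at 1313, 667, 1463, 643, 1065 and 26.7 CPM, while FTH1, which stores iron, stood at 943, 711, 462, 703, 1360 and 3174. FTH1 was not particular to macrophages in the deepest run of E280, at 3396 CPM in endothelium-like nuclei and 1904 in cluster 22. It stood at 889 in uterine epithelium-like and 869 in uterine stroma-like nuclei. CD74, of antigen presentation, stood at 129, 284, 164, 156, 178 and 32.9 CPM. The 2 macrophage clusters of E280 were unlike each other in its deepest run: cluster 13 had 4.64 CPM of CD74, 298 of CCL2, 50.1 of PTGS2, 623 of CD36 and 35.2 of SLC40A1, and cluster 28 had 105, 1217, 483, 1321 and 3.31.

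Clusters 7 (2328 nuclei, 1205 of them at E60) and 17 (829 nuclei, 737 at E240) held transcripts of both sides of the placenta and stayed without a name. PAG17, a binucleate cell glycoprotein, stood at 3006 and 2899 CPM in them, and PAX8, a transcription factor of uterine epithelium, at 329 and 369. SLIT2, the abundant guidance gene of binucleate-like nuclei (12100 CPM in cluster 15), stood at 162 and 397. The median share of mitochondrial UMIs was 0.831% in cluster 7, against 0.028% to 0.093% over all nuclei of a stage.

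Of the tests that follow, only the ratio of median fractions was chosen before its result was seen; all others, the splits included, were chosen afterwards.

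Uterine epithelium-like nuclei carried transcripts of binucleate cells at every stage. Free RNA spread evenly over the droplets would load all classes alike. The stages were grouped by the ratio of the uterine epithelium to the highest of 4 other classes, after it was seen. At E60, E240 and E280 the lowest ratio was 2.556, which argues against such evenly spread RNA as the whole source there. At E85, E110 and E180 the highest ratio was 1.116, and free RNA cannot be told apart from a real signal there. Doublets with a binucleate nucleus would bring its other abundant genes too: these reached 0.0919 of the marker genes' median fraction, but the bootstrap interval (0.0009 to 0.8504) passes the limit of 0.5, so by this ratio doublets cannot be told apart. For the next comparison the stages were again grouped after their values were seen. Other abundant genes over markers were summed and taken above the level of each of the 4 other classes. At E60, E180 and E240 they reached at most 0.5457 of the lowest binucleate cluster's ratio (upper limit with counting error). This argues against doublets with nuclei of the named binucleate clusters as the whole source at those stages. Unnamed clusters 7 and 17 were not compared. They held PAG17 at 3006 and 2899 CPM but SLIT2 at only 162 and 397, and mixing with droplets of that kind was not tested. At E85 and E110 they reached at most 2.458, and doublets cannot be told apart there. At E280, with 11 binucleate-like nuclei, doublets were not tested, and no biological explanation was tested at any stage.

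Almost no trophoblast-like nuclei were found at E280. A failure of the naming would leave their markers in some other class. Of 18 markers, 7 stood below 15% of their trophoblast level in uterine epithelium, uterine stroma, endothelium, macrophage and smooth muscle over E60 to E240. Over all nuclei of E280 these 7 stood at a median of 0.0268 of their lowest earlier level. That median and the 5 markers below 0.25 (GATA3, PAG2, PAG8, PAG11 and PAG12) argue against trophoblast nuclei that kept these markers under another name. The naming used the same marker set, so trophoblast nuclei that had lost these markers would be missed here too. The others of the 7 were TFAP2A (0.664), which uterine epithelium-like nuclei also carried, and VGLL1 (1.21). A sample of mostly maternal tissue would lower every class of the fetal side. DLK1 endothelium and mesenchymal nuclei were taken as such classes, an assumption that was not tested. Together they made 0.174% of nuclei at E280, 0.2518 of the lowest earlier share (0.691% at E180). Mesenchymal nuclei were already at 1 of 10271 at E180, where trophoblast-like nuclei made 13.5%, so this ratio rests on the DLK1 endothelium. Under that assumption a piece of mainly maternal tissue is a candidate explanation. The stage itself stays open and untested, since E280 is 1 sample.

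The 6 samples can be split into groups of 3 in 10 ways, too few for a share under 0.05. With 0 calls in a real split, every split gives as many, so the counts that follow decide nothing. In endothelium-like nuclei edgeR called 0 in the real split and at most 0 in another (552 and at most 595 genes at an unadjusted p under 0.05; DESeq2 called 40 in the real split). In uterine epithelium-like nuclei it called 0 and at most 0 (1120 and at most 800; DESeq2 295). In uterine stroma-like nuclei the highest other split, E60, E240 and E280 against E85, E110 and E180, called 43 genes against 0 (524 and at most 606; DESeq2 87).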
